A study of Danio rerio with 18 samples.

How the data were processed

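Liver RNA of first-generation zebrafish of the AB line, exposed chronically to 0, 0.01 or 1 µg/L imatinib mesylate, was measured on 18 one-colour Cy3 Agilent arrays, 3 per dose and sex. Each array holds a pool of 1 or 2 fish, and 3 pools hold a single fish. The number of arrays limits the precision.

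Per the file headers, the scanner values are intensities from Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended within the array, with low spots set to a surrogate and no normalization between arrays. Per the file headers, the other columns used are the mean foreground and median background intensity of a spot and 0 or 1 flags per spot. The deposited matrix holds log2 values that the authors normalized between arrays with limma in R 2.15.1. The method is not stated, and these log2 values served as an alternative only. Probe positions per the file headers refer to Zv9 (danRer7).

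The log2 of the processed signal minus the 75th percentile of the array was used. Outlier spots were set missing, spots of a probe were averaged, and probes well above background on all 3 arrays of at least 1 group were kept, 32711 of 43603. For each gene symbol the probe with the highest mean was taken, giving 19714 features, 13399 of them with a symbol. Where no array of a group measured a probe well above background, on its own or within an average, a bound ("at least") is given from the lowest level measured above background on each array, or no size if the other side held such a group too or lay too low for a bound above 1. No size is given for a difference between the sexes that rests on such a group.

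Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A limma fit of the 6 group means over all 18 arrays (12 residual degrees of freedom) gave two-sided moderated tests of 10 contrasts, each adjusted by Benjamini-Hochberg with a threshold of 0.05. Dose effects were averaged over the sexes, tested within each sex and compared between the sexes. Gene lists fixed before the data were examined, 34 with at least 5 tested members, were tested with camera (correlation 0.01, or estimated) and fry. The ribosomal list, chosen by symbol pattern, also took the rps6k kinase genes and rps27l. The estrogen-responsive list shares zp2.1, zp2.2, zp2.3, zp3 and zp3b with the oocyte list. The method was tested on simulated data. Of 100 features with a log2 change of 1 it recovered 30 for the low dose and 34 for the high dose against control. With a change of 2 it recovered 82 and 84, and 59 and 48 for the low dose in females and males.

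Genes to name were chosen by a rule set before the data were examined. For each dose against control these were the 12 higher and 12 lower genes with a symbol and the smallest p among those past the threshold with the same sign in both sexes, or, where fewer than 10 passed, 5 and 5 by p, said not to have passed. For the high against the low dose, within a sex and for the differences between the sexes 5 and 5 were taken, and for females against males the 10 and 10 with the largest fold past the threshold. Up to 4 members of each list with the smallest p were added. A few results that the rule selects are withheld and not given. A gene lay on the side of a change in a pool when it differed that way from the reference mean of its sex, or, for females against males, when a female pool differed that way from the mean of all male pools.

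Alternatives were array weights, normexp background correction (offset 50, and 1, added after the data were seen; "normexp" alone means 50), quantile normalization, the deposited values, no filter and a filter on all 18 arrays, the mean of a gene's probes, eBayes with trend and robust settings, a replicate block, a slide block, only the arrays compared, leaving out the single-fish pools, the 2 arrays high in oocyte transcripts (added after the data were seen) or each array in turn, split controls, and an adjusted p under 0.1. The slide was a fixed block for the low dose, for females against males and for the differences between the sexes, and a random block for the contrasts with the high dose, which shares no slide with the other doses. Normexp started from the mean foreground and median background without detrending, and its offset was added before the scaling.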

Results

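Liver RNA of zebrafish was profiled after chronic exposure through the water to imatinib mesylate, a tyrosine kinase inhibitor given against leukemia. Fish of the AB line received 0, 0.01 (low dose) or 1 µg/L (high dose). Liver RNA pools of 1 or 2 fish each were hybridised to 18 one-colour arrays, 3 female and 3 male pools per dose, so that a dose comparison averaged over the sexes set 6 pools against 6. Between 62.8% and 84.1% of the probe spots of an array were well above background, and no spot was saturated. Pools of one group correlated across features with r between 0.90 and 0.98, and the 2 largest components held 32.3% and 14.6% of the variance. Levels are log2 signals relative to the 75th percentile of the array, SE is that of the fitted difference, and probe positions refer to Zv9 (danRer7). The number of arrays limits the precision of every value.

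The first comparison asked whether the low dose altered liver transcripts. At 0.01 µg/L, per2, a light-induced repressor of the circadian clock (chromosome 2, 48424815 to 48424874), rose 3.35-fold, with a log2 change of 1.74 (SE 0.258, n = 6 against 6, limma adjusted p = 0.0244). Its level went from -1.92 ± 0.56 (SD) in controls to -0.18 ± 0.44, higher in 6 of 6 exposed pools. The tight junction gene cldn8.1 fell at least 6.36-fold (adjusted p = 0.0161), and comtb, for a methyltransferase that inactivates catecholamines and catechol estrogens, fell at least 3.89-fold (adjusted p = 0.0161). The antigen-presenting mhc1uba fell at least 4.46-fold (adjusted p = 0.0465). Only 1 of 6 low-dose arrays measured each of these 3 probes well above background, against 6 of 6 control arrays. The zinc finger gene znf1141 fell by 1.19 (adjusted p = 0.0465), and olfm1a, for a secreted olfactomedin, fell by 1.68 (adjusted p = 0.0161), although 1 of its 2 probes moved that way. All 6 genes lay on the same side in 6 of 6 pools.

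Other genes with a small p did not pass at the low dose. They were dynll2b, for a dynein light chain (0.88, adjusted p = 0.0538), cenpv, for a centromere protein (1.12), dnajb9a, for a co-chaperone of the endoplasmic reticulum (2.11), and the amino acid transporter gene slc38a5a (1.74), each of the last 3 with an adjusted p = 0.0601. The value of slc38a5a was -0.10 with the slide as a block. In all, 13 of 19714 features passed, 3 higher and 10 lower, 6 of them with a gene symbol, and 2615 had an unadjusted p under 0.05. With the slide as a block 0 features passed in limma (725 at an unadjusted p under 0.05) and per2 stood at 0.85, as it did when its 3 probes were averaged. None of the 6 named genes that passed held with normexp background correction, without the single-fish pools or without the 2 arrays high in oocyte transcripts. No feature was left without control male pool 1 (2140 at an unadjusted p under 0.05) or 3 (2691), or without low-dose male pool 2 (2160) or 3 (2574), and 1 was left without low-dose female pool 2 or 3. The count was 5 without high-dose male pool 2 or 3, 6 without high-dose female pool 1, 8 without control male pool 2 and 50 without high-dose male pool 1. The deposited values gave 2 higher and 4 lower features, and normexp 1 and 1. The median of all features was -0.18 with normexp.

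Members of the gene lists were examined at the low dose as well. Of 27 cholesterol synthesis genes, 0 passed in limma over all genes and 13 were higher when adjusted over the list alone, with a median log2 change of 0.94. The smallest p belonged to hmgcra (1.34, SE 0.321), the rate-limiting reductase of the pathway, mvda (1.92, SE 0.534), cyp51 (1.75, SE 0.501) and mvk (1.45, SE 0.414). Of 38 endoplasmic reticulum stress genes, 0 passed over all genes and 8 were higher when adjusted over the list alone. They included dnajb9b (1.78, SE 0.344), creld2 (1.26, SE 0.313) and hspa5 (3.03-fold, SE 0.441 on the log2 scale), for the main chaperone of that compartment. The median of this list was 0.48, and -0.32 with the slide as a block. In the heat shock list 0 of 28 genes passed over all genes and 1 was lower when adjusted over the list alone. Its smallest p values belonged to hsf1 (-1.35), the transcription factor of the response, and the chaperone gene hsp70.3 (1.94). The replication helicase genes mcm6 (1.68, SE 0.343) and mcm3 (1.76, SE 0.376) were the 2 of 60 cell cycle genes that were higher when adjusted over the list alone, while the median of the list was -0.53, and 0.59 with the slide as a block. In the circadian clock list 1 of 38 genes passed over all genes, per2, and 4 were higher and 3 lower when adjusted over the list alone. These included nfil3-5 (1.15, SE 0.280), bhlhe40 (-1.13, SE 0.238) and dbpb (-1.33, SE 0.308), and fry's test for change in either direction gave an adjusted p of 1.3e-05, the smallest of 5 lists it called. When adjusted over the list alone, 1 conjugation gene was higher and 1 lower, 1 proteasome gene was lower and 1 iron and heme gene was higher, against 0 over all genes.

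Camera with its preset correlation placed 5 of 34 lists apart from other genes at the low dose. Cholesterol synthesis (adjusted p = 4.74e-10), endoplasmic reticulum stress (3.83e-08) and heat shock (0.0265) were up, and the markers of oocytes (median -2.85, 0.0081) and exocrine pancreas (median -0.55, 0.0265) were down. None of the 5 held when the correlation was estimated, where each had an adjusted p = 0.971. With the slide as a block the calls of endoplasmic reticulum stress, heat shock and exocrine pancreas ended. The median of heat shock then went from 0.18 to -0.18 and that of exocrine pancreas from -0.55 to -0.68. In females these blocked values rest on control male pool 1, the only tie between slide 1, which holds all control females, and the other slides. In males they rest on low-dose female pool 3, the only tie between slide 3, which holds all low-dose males, and the slides of the control males. The array of low-dose female pool 3 was also the only one that the scanner's quality report marked for evaluation. The same block brought calls of cell cycle up (adjusted p = 3.17e-10) and of oxidative phosphorylation (median -0.49, 1.16e-08), the proteasome (median -0.55, 4.4e-06), ribosomal proteins (0.00234) and fatty acid oxidation (0.00234) down. Oocyte transcripts were high in control male pool 1, and with the slide as a block that list was called up, with a median of 4.00 (adjusted p = 1.76e-07). Normexp ended the call of exocrine pancreas (-0.36) and called 18 lists, and leaving out the 2 arrays high in oocyte transcripts ended the calls of heat shock and oocytes.

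The comparison of the high dose with control asked for the response to the larger exposure. All high-dose arrays lay on slides without control or low-dose arrays, so that dose and slide cannot be told apart in it. The gene tdo2b (chromosome 11, 34920941 to 34921000), for a tryptophan dioxygenase of hepatocytes, fell 10.6-fold, by 3.40 on the log2 scale (SE 0.429, n = 6 against 6, limma adjusted p = 0.00113), from 5.01 ± 0.86 (SD) to 1.61 ± 1.47. The related gene tdo2a stood higher, between 6.72 and 7.71 in control pools and between 5.93 and 7.51 in high-dose pools. The clock repressor per2 rose 4.60-fold (SE 0.258, adjusted p = 0.000707). The gene nfil3-5 (chromosome 6, 9616264 to 9616323), for a repressor of clock output genes, rose 4.68-fold (2.23, SE 0.280, adjusted p = 0.00113). The squalene epoxidase gene sqlea (chromosome 16, 46192859 to 46192918) rose 10.9-fold (3.45, SE 0.734, adjusted p = 0.0118), and mcm6 (chromosome 6, 12896802 to 12896861) rose 5.01-fold (adjusted p = 0.00200). Each of these genes lay on that side in 6 of 6 pools. In all, 1621 of 19714 features passed, 1153 higher and 468 lower, 986 of them with a gene symbol. The deposited values gave 948 higher and 705 lower, a share of 57.4% against 71.1%, and normexp background correction left 145 and 66. Leaving out high-dose female pool 2 gave 809 features, high-dose male pool 2 gave 877 and control male pool 2 gave 1032.

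The 12 genes with the smallest p that rose in both sexes also included tmtops2a, for a light-sensing opsin of peripheral tissues (at least 3.32-fold, adjusted p = 0.000507), and the homeobox gene irx1a (1.95, SE 0.210). With them rose the growth factor receptor-like gene fgfrl1b (1.53, SE 0.169), the calpain protease gene capn12 (2.03, SE 0.225), cdcp2 (1.54, SE 0.172), for a CUB domain protein, and lingo4a (2.36, SE 0.272), for a leucine-rich repeat membrane protein. The sodium channel gene scn5lab (2.01), lhfpl5b, for a tetraspan membrane protein of hair cells, the neurofilament gene nefmb (at least 2.44-fold) and the water channel gene aqp8b (at least 2.14-fold) completed them. Of 6 control arrays, 1 measured tmtops2a well above background, 1 lhfpl5b (with 3 of 6 high-dose arrays, so that no size is given), 2 nefmb and 3 aqp8b. With normexp background correction tmtops2a, irx1a, capn12, cdcp2, scn5lab, lhfpl5b, nefmb and aqp8b no longer passed, whereas fgfrl1b, lingo4a, per2 and nfil3-5 did, and irx1a also lost its call with the mean of its probes. On the lower side, klhl24b, for an adaptor of a ubiquitin ligase, fell by 1.86 (SE 0.238), and flcn, for the nutrient sensor folliculin, by 0.99 (SE 0.128). The chromatin reader gene ing5a (-1.39), the fatty acid hydroxylase gene cyp2u1 (-1.64, SE 0.252), the retinoid X receptor gene rxrgb (-1.20) and gpr157 (-0.96), for a receptor of cilia, fell too. The genes ubald1a (-1.14), znf395b (-1.40), wbp1 (-1.07), ttc14 (-1.08) and nt5dc2 (-1.19) completed the 12 with tdo2b, and among these 12 only ttc14 lost its call with normexp. Of the 58 genes named for this comparison, here or by list, 55 lay on the side of the fold change in every high-dose pool, and creld2, vtg6 and txnipa in 5 of 6.

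**Figure D1:**
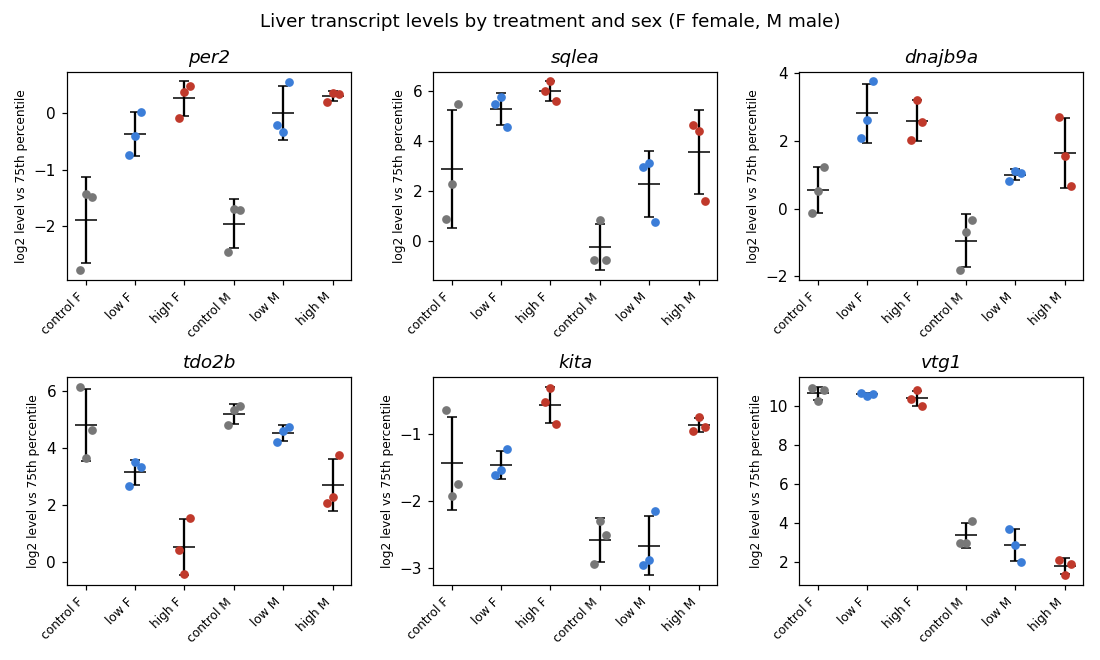
Levels of 6 genes in each liver pool (log2 signal relative to the array's 75th percentile, vertical axis) by dose and sex; points are the 3 pools of a group, the dash is their mean and the bars their SD. The per2 mean was -1.92 in controls and -0.18 at the low dose, and vtg1 separates the sexes.

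Cholesterol synthesis genes made up the largest share past the threshold of any list at the high dose. Of 27 genes, 15 rose in limma over all genes, 0 fell and 12 did not pass, and 21 rose when adjusted over the list alone, with a median of 1.44. Besides sqlea these included hsd17b7 (2.06, SE 0.376, adjusted p = 0.00583), mvk (2.21, SE 0.414) and the sterol demethylase gene cyp51 (4.94-fold). Of 38 endoplasmic reticulum stress genes 6 rose, or 8 when adjusted over the list alone. The smallest p belonged to dnajb9b (chromosome 4, 16889759 to 16889818; 2.31, SE 0.344, adjusted p = 0.00208), dnajb9a (2.32, SE 0.398), creld2 (1.47, SE 0.313) and hspa5 (2.00, SE 0.441). Of 60 cell cycle genes 9 rose, or 12 when adjusted over the list alone, led by mcm6, mcm3 (2.35, SE 0.376), mcm5 (1.99, SE 0.424) and the replication clamp gene pcna (1.61, SE 0.344). In the DNA damage list 2 of 51 genes rose, among them the checkpoint kinase gene chek1 (at least 2.58-fold). There 3 fell, among them the pro-apoptotic bbc3 (at least 2.5-fold lower) and casp9 (-0.97, SE 0.265), with the same counts when adjusted over the list alone. Without the single-fish pools hspa5, mcm5, pcna, chek1 and casp9 did not pass. The call of casp9 held in 7 of 18 fits that left out an array, and not with the replicate block, with the slide as a block or without the 2 arrays high in oocyte transcripts. Nor did cyp51 pass without those 2 arrays, cyp51 and creld2 with array weights, or chek1 with the replicate block. Well above background were 2 of 6 control arrays for chek1 and 3 of 6 high-dose arrays for bbc3.

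Camera placed 7 of 34 lists apart from other genes at the high dose with its preset correlation. Cholesterol synthesis (adjusted p = 1.89e-08), endoplasmic reticulum stress (2.41e-05) and cell cycle (0.00169) were up. Ribosomal proteins (1.83e-06), estrogen-responsive genes (0.00169), intestine markers (0.0036) and hepatocyte markers (0.0179) were down. None held with an estimated correlation, with an adjusted p = 0.86 for the estrogen-responsive genes and 0.955 for the other 6. The calls of the ribosomal proteins (median from -0.21 to -0.03), hepatocyte markers (-0.16 to -0.02) and intestine markers (-1.03 to -0.98, adjusted p = 0.0663) ended with quantile normalization. With normexp those of the intestine (-0.56) and hepatocyte markers (-0.08) ended too. Normexp brought calls of heat shock, the proteasome, endocrine pancreas and muscle and adipose markers up, and leaving out the 2 arrays high in oocyte transcripts those of oxidative phosphorylation and oocyte markers down. Part of the estrogen-responsive list, its zp genes, also counts among the oocyte markers.

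Clock genes moved in both directions at the high dose. In the circadian clock list 4 of 38 genes rose and 7 fell over all genes, 9 and 10 when adjusted over the list alone, and fry's test for change in either direction gave an adjusted p of 4.41e-11, the smallest of 9 lists it called. Besides per2 and nfil3-5, the clock-output transcription factor gene dbpb fell by 1.77 (SE 0.308, adjusted p = 0.00453) and ciarta, for a repressor of the clock, by 1.31 (SE 0.217, adjusted p = 0.00343). The list written for imatinib targets had 8 tested genes, without abl1 or bcr. They were kita, abl2, pdgfra, lck, pdgfrb, ddr2a, csf1ra and nqo1, which the oxidative stress list also holds. Of these, kita (chromosome 20, 22408353 to 22410154), for a Kit receptor tyrosine kinase, rose 2.45-fold (1.29, SE 0.227, adjusted p = 0.00474) in 6 of 6 pools. It was the only one to pass, by either adjustment, and the mean of its 2 probes, which moved in opposite directions, gave 0.43. The yolk protein precursor genes vtg5 (-1.13, SE 0.271, adjusted p = 0.0208) and vtg6 (-0.99, SE 0.271, adjusted p = 0.0377) fell, 2 of 18 estrogen-responsive genes over all genes and 4 when adjusted over the list alone. Without high-dose male pool 2, without the 2 arrays high in oocyte transcripts or with the replicate block neither passed. The call of vtg6 held in 9 of 18 fits that left out an array, and also ended without control female pool 1 or 3, control male pool 2 or 3, low-dose female pool 2, high-dose female pool 1 or 3, or high-dose male pool 3, without the single-fish pools and with the slide as a block. The heme synthesis genes cpox (0.99, SE 0.175) and hmbsa (1.05, SE 0.192) rose among 27 iron and heme genes, of which 2 were higher and 1 lower when adjusted over the list alone.

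Few genes of drug handling and intermediary metabolism passed at the high dose. Of 34 cytochrome P450 genes, cyp2u1 alone fell, by either adjustment. The sulfotransferase genes sult1st1 (1.90, SE 0.511) and sult1st6 (0.69, SE 0.199) were the 2 of 40 conjugation genes that rose, against 0 when adjusted over the list alone. Of 16 drug transporters, the organic anion transporter gene slc22a7b.1 (at least 2.73-fold higher; well above background on 2 of 6 control arrays) alone passed, by either adjustment. The redox regulator gene txnipa (-0.95, SE 0.241) did so among 36 oxidative stress genes. In the heat shock list dnajb1a (0.65) rose and hsf2 (-0.71) and st13 (-0.54) fell among 28 genes, with 2 higher and 2 lower when adjusted over the list alone. The lipogenic regulator gene srebf1 (1.04, SE 0.218) rose among 27 fatty acid synthesis genes. The hexokinase gene hk1 (1.19) rose and the insulin receptor gene insra (-0.71) fell among 46 carbohydrate genes, and these 3 calls were the same over each list alone. For interferon response 2 of 30 genes were higher, for the proteasome 2 of 52, for oxidative phosphorylation 1 of 88 and for growth hormone signalling 1 of 22. When adjusted over the list alone these were 0, 0, 0 and 1. No member passed, by either adjustment, in the lists of fatty acid oxidation (34 tested), acute phase (53), bile acid and lipoprotein (33) or ribosomal proteins (91). With normexp bbc3, casp9, chek1, creld2, dbpb, dnajb1a, hk1, hsf2, insra, pcna, slc22a7b.1, srebf1, st13, sult1st1, sult1st6, txnipa, vtg5 and vtg6 no longer passed. Without the single-fish pools dnajb1a, hk1, hsf2, srebf1, st13, sult1st1, sult1st6 and txnipa did not pass, nor did dnajb1a, hsf2, slc22a7b.1, sult1st6 and txnipa without the 2 arrays high in oocyte transcripts. The replicate block ended the calls of dnajb1a, hsf2, st13, sult1st1, sult1st6 and txnipa, the slide as a block those of dnajb1a, sult1st1 and sult1st6, array weights those of dnajb1a, slc22a7b.1 and sult1st6, and the mean of its probes that of insra. Of 18 fits that left out an array, sult1st6 passed in 6, sult1st1 in 8, and dnajb1a and st13 in 10 each.

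Markers of other tissues differed between pools within groups. Intestine markers had a median change of -1.03 at the high dose, where 0 of 22 passed by either adjustment in limma. Their level was -0.64 in high-dose female pool 1 and -1.55 in pool 2 against 3.50 in pool 3. Oocyte markers (0 of 15 passed, median -1.78) stood at 5.44 in control male pool 1 and 5.22 in high-dose female pool 1. No gene passed by either adjustment among the markers of testis (12 tested), exocrine pancreas (31), endocrine pancreas (11), lymphocytes (17) or macrophages and neutrophils (31). Exocrine pancreas levels lay between 2.609 and 6.755 over all pools and between 3.558 and 6.719 in high-dose females, with hepatocyte levels between 7.304 and 9.124. Of 23 erythrocyte genes 2 rose, of 33 stellate, endothelial and biliary genes 1 rose, and of 28 hepatocyte genes tdo2b alone fell, with the same counts over each list alone. The fast muscle genes tnni2a.4 (0.76, SE 0.202) and mylpfb (0.55) rose among 21 muscle and adipose genes by either adjustment, and neither passed with normexp, with the deposited values, with the replicate block or without the single-fish pools. Of 18 fits that left out an array, mylpfb passed in 8 and tnni2a.4 in 12.

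**Figure D2:**
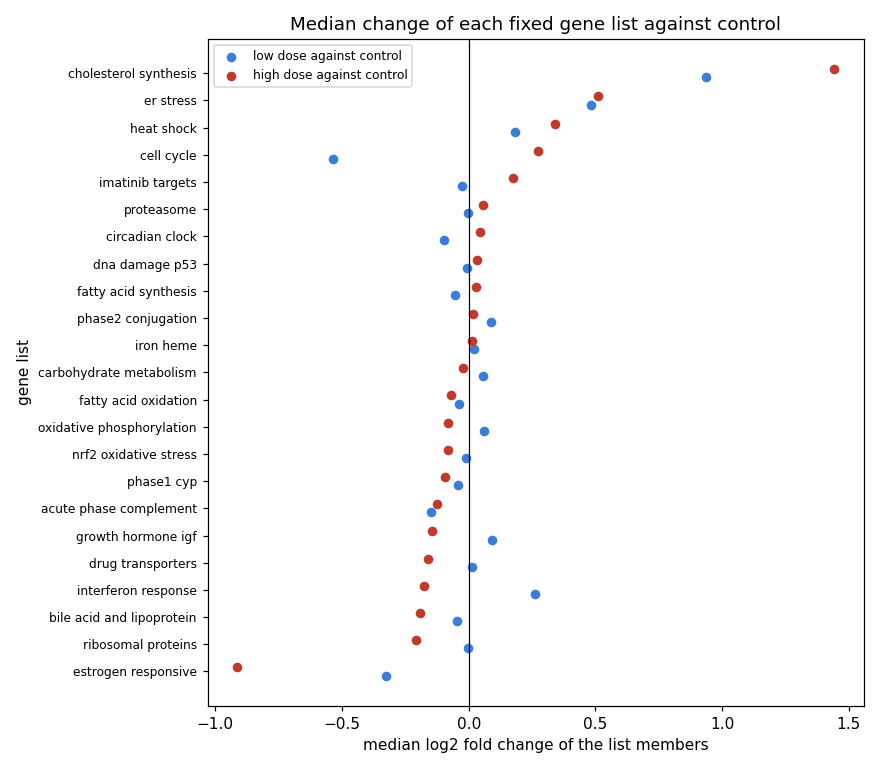
Median log2 fold change of the members of each pathway list (horizontal axis) at the low dose and at the high dose against control, 1 line per list. Cholesterol synthesis stands at 0.94 and 1.44.

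The high dose was also set against the low dose, 6 pools against 6, to see what the higher concentration added. The heme synthesis gene hmbsa was 2.45-fold higher at the high dose (1.29, SE 0.192, limma adjusted p = 0.00192) and kita 2.54-fold higher (1.35, SE 0.227, adjusted p = 0.0041), though by 0.70 and without a call when its 2 probes were averaged. The gene hmox1a, for the oxygenase that breaks heme down (chromosome 3, 27021597 to 27023156), fell by 1.89 (SE 0.378, adjusted p = 0.0108), and tdo2b fell by 2.23 (SE 0.429, adjusted p = 0.0086). The transferrin receptor gene tfr1a was at least 1.79-fold higher (adjusted p = 0.0383; well above background on 3 of 6 low-dose arrays). The smallest p belonged to the odorant receptor gene or109-6 (at least 3.74-fold, adjusted p = 0.000191), cdcp2 (1.69, SE 0.172), capn12 (2.17, SE 0.225), exoc1l (at least 2.37-fold), of the vesicle-tethering exocyst family, and the homeobox gene alx1 (2.01, SE 0.243). Low-dose arrays measured or109-6 and alx1 well above background on 3 of 6 and exoc1l on 1 of 6. On the lower side were ttc14 (-0.93), dedd1 (-1.05), for a death effector domain protein, and the autophagy kinase gene ulk1a (-1.30), of which 1 of 2 probes moved that way. The cell cycle gene cenpf (0.75), srebf1 (0.99) and the glucose transporter gene slc2a1a (1.08; well above background on 2 of 6 low-dose arrays) were also higher, and all 16 genes lay on their side in 6 of 6 pools. In all 873 features passed, 833 higher and 40 lower, against 30 and 2 with normexp. Of the 16 genes, hmbsa, kita and tdo2b kept their calls with normexp and 9 kept theirs without the single-fish pools. The call of cenpf held in 6 of 18 fits that left out an array, that of tfr1a in 7 and that of slc2a1a in 11. With the deposited values and with quantile normalization these 3 did not pass, nor did cenpf and tfr1a with the replicate block or the slide as a block, nor cenpf without the filter. The replicate block also ended the call of dedd1, and the mean of a gene's probes those of cenpf, dedd1, kita and ulk1a. Leaving out high-dose female pool 2 gave 494 features, high-dose male pool 2 gave 549 and low-dose female pool 2 gave 581. Camera called 7 lists, none with an estimated correlation, where each had an adjusted p = 0.963.

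Within females, tdo2b was 19.8-fold lower at the high dose, by 4.31 (SE 0.606, n = 3 against 3, limma adjusted p = 0.0164), from 4.82 ± 1.26 (SD) to 0.51 ± 0.99. The chaperone genes dnajb9b (2.64, SE 0.486, adjusted p = 0.0264), creld2 (2.04, adjusted p = 0.0328) and hspa5 (2.55, adjusted p = 0.0483) rose. So did mvk (2.95, adjusted p = 0.0295), mcm6 (2.38, adjusted p = 0.0303) and pcna (2.28, adjusted p = 0.0328), and cyp2u1 fell by 1.62 (adjusted p = 0.0338). The smallest p among higher genes belonged to the nuclear pore gene nup153 (at least 1.51-fold), irx1a (2.00), aqp8b (at least 1.88-fold), capn12 (4.29-fold) and the corepressor gene tle3b (1.80; well above background on 1 of 3 control arrays). The values of nup153, aqp8b and tle3b were negative with normexp. On the lower side were ndufa3 (-1.20), of respiratory complex I, the immune receptor gene dicp1.7 (-1.37), abhd17ab (-2.35), for a depalmitoylase, and olfm1a (-1.89), the last pair with 1 of 2 probes on that side. All 17 genes lay on their side in 3 of 3 pools, and hspa5 passed in 5 of 18 fits that left out an array. With the slide as a block creld2, cyp2u1, hspa5 and pcna did not pass. Of 433 features 250 were higher and 183 lower. No feature passed in limma with normexp (2028 at an unadjusted p under 0.05), with only the arrays compared (2915), without the single-fish pools (3293), without the 2 arrays high in oocyte transcripts (3321), or without high-dose female pool 1 (3039) or 2 (3092), and 1419 passed without pool 3. The count was 72 without control female pool 2, 99 without control female pool 1 and 272 without high-dose male pool 3. The median of all features was -0.24 with normexp.

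Within males, nfil3-5 was 8.48-fold higher at the high dose (SE 0.396, n = 3 against 3, limma adjusted p = 0.00454). The gene kita was higher by 1.71 (SE 0.321, adjusted p = 0.0192), or by 0.89 without a call when its 2 probes were averaged. The yolk precursor transcript vtg5 (chromosome 22, 25223664 to 25223723), at 4.31 ± 0.27 (SD) in control males, fell 3.47-fold to 2.52 ± 0.67 (-1.79, SE 0.383, adjusted p = 0.0312). The heme genes cpox (1.39, adjusted p = 0.0169) and hmbsa (1.38, adjusted p = 0.0230), hmgcra (2.02, adjusted p = 0.0412) and dnajb9a (2.59, adjusted p = 0.0340) rose. So did mcm6 (2.27, adjusted p = 0.0312) and mcm3 (2.34, adjusted p = 0.043), and cyp2u1 fell by 1.66 (adjusted p = 0.032). The smallest p on the higher side belonged to fgfrl1b (1.94), nfil3-5, the homeobox gene six5 (at least 1.64-fold), vash2, for a tubulin carboxypeptidase (1.63), and lingo4a (2.81). On the lower side it belonged to fbxw11a (-2.02), of a ubiquitin ligase and with 1 of 2 probes on that side, ubald1a (-1.35), flcn (-1.04), rxrgb (-1.49) and nt5dc2 (-1.42). All 19 genes lay on their side in 3 of 3 pools. With the mean of a gene's probes fbxw11a, hmbsa, hmgcra, kita, mcm3 and mcm6 did not pass. Of 306 features 265 were higher and 41 lower, against 153 and 63 with quantile normalization, 254 and 108 with the deposited values, and 10 and 3 with normexp. With only the arrays compared 0 passed in limma (3159 at an unadjusted p under 0.05), with the replicate block 52 and without the 2 arrays high in oocyte transcripts 66, the last pair with 7 of the 19 genes each. The call of hmgcra held in 6 of 18 fits that left out an array and that of mcm3 in 8. The count was 22 without high-dose male pool 2, 83 without control male pool 2, 91 without control male pool 1, 96 without high-dose male pool 1, 106 without pool 3 and 164 without control male pool 3. The median change of all features was 0.12. In the estrogen-responsive list 1 of 18 genes fell over all genes and 5 when adjusted over the list alone. The fry test of that list gave an adjusted p of 0.0204, and camera an adjusted p = 0.0796 with an estimated correlation. That list includes the oocyte markers zp2.1, zp2.2, zp2.3, zp3 and zp3b, which were high in control male pool 1. For zp3 the level there was 7.39, against at most 2.46 in the other male pools. Neither of these 2 tests was repeated without that pool, so they do not show an estrogen response apart from it.

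At the low dose within females, olfm1a fell by 2.61 (SE 0.320, n = 3 against 3, limma adjusted p = 0.00821; 1 of 2 probes on that side). The sarcospan gene sspn, of the dystrophin complex, was called lower (adjusted p = 0.0413), but 0 of 3 exposed and 1 of 3 control arrays were well above background, so that no size is given. The call of sspn ended with the deposited values, with trend and robust eBayes, without the filter and in most fits that left out an array. Of the other genes with the smallest p, none passed. They were cenpv (1.85), dynll2b (1.26), the neuropeptide gene npffl (at least 2.35-fold higher, with a negative value under normexp), the ethanolamine kinase gene etnk2 (4.93-fold), fam118b (1.36), abhd17ab (-1.92), ikbip (-2.10) and znf1141 (-1.60). In males comtb passed (at least 5.57-fold lower, adjusted p = 0.0483), lower in 3 of 3 pools as olfm1a and sspn were in females. The fucosyltransferase gene fut7 (at least 10.4-fold higher), per2 (1.96), the transcription factor gene klf4 (2.59), nfil3-5 (1.92), myo1ha (2.03; well above background on 1 of 3 control arrays), trim35-9 (-3.63), or109-6 (at least 1.61-fold lower) and cldn8.1 (-2.73; on 1 of 3 exposed arrays) did not pass in males. Nor did the forkhead gene foxi3a, given no size with 0 of 3 exposed arrays well above background. In females 3 features passed and in males 2, all lower, with 2187 and 1379 at an unadjusted p under 0.05. In females the count was 0 without control female pool 2 (2232 at an unadjusted p under 0.05) or low-dose female pool 3 (1298), 1 without low-dose female pool 2, 6 without control female pool 1 and 32 without high-dose male pool 1. In males it was 0 without control female pool 1 or 3, any control male pool, low-dose male pool 2, high-dose female pool 1 or any high-dose male pool, with 853 to 1876 at an unadjusted p under 0.05. It was 1 without control female pool 2, low-dose female pool 2, low-dose male pool 3 or high-dose female pool 2, and 4 without high-dose female pool 3. Neither olfm1a, sspn nor comtb passed with the slide as a block. The median of all features in females was -0.32 with normexp.

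Whether the sexes responded differently was tested as the female effect minus the male effect. This test misses most differences of the sizes simulated. Of 100 features with a log2 difference of 1 it recovered 0 at the low and 1 at the high dose. With a difference of 2 it recovered 11 and 23. No feature passed at the low dose in limma (smallest adjusted p = 0.336, 954 at an unadjusted p under 0.05). On the side of a lower effect in females the smallest p belonged to paplnb (-2.27), tmem220 (-3.14), sspn, fut7 and the membrane linker gene msnb. On the other side were ccdc62 (1.42), fbxw9 (1.72), kansl2 (1.16), trim35-9 and the phosphatase gene ppef1, which was negative with normexp. No size is given for sspn, fut7, msnb, trim35-9 and ppef1, which no array of at least 1 of the 4 groups compared measured well above background. At the high dose 2 features passed, a probe without a gene symbol (adjusted p = 0.00362) and zgc:172170 (adjusted p = 0.0169), named after its values were seen. Both were well above background on the 3 high-dose male arrays and on no other array, so that no size is given. Neither abhd17ab (-2.83), msnb, dicp1.7 (-1.95) and ndufa3 (-1.61), each with an adjusted p = 0.122, nor olfm1a (-2.40) passed. The same held for tedc1 (1.39), ofd1 (1.80), raver1, bsnd and the phosphatase gene dusp4, and raver1 and bsnd were negative with normexp. For msnb, raver1, bsnd and dusp4 no size is given for the same reason as above. For tdo2b, which passed in females, the difference was -1.81 (SE 0.858, adjusted p = 0.45), and for vtg5 and kita, which passed in males, 1.33 (adjusted p = 0.412) and -0.85 (adjusted p = 0.494). Camera called 11 lists at the low dose and 9 at the high dose, none with an estimated correlation (smallest adjusted p = 0.811 and 0.493). When adjusted over the list alone, 0 genes passed at the low dose and 14 were lower at the high dose, 10 of them among 22 intestine markers, with 0 over all genes. The count at the high dose was 95 without high-dose female pool 3 and 67 without high-dose male pool 1. It was 1 without control female pool 2, control male pool 1 or 2, high-dose female pool 1, or high-dose male pool 2 or 3, and at the low dose it was 1 without control female pool 2 or low-dose female pool 1. The median of all features was -0.11 at the high dose, and -0.26 with normexp, and -0.24 with normexp at the low dose.

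Both dose comparisons used the same 6 control pools. All 13 features called at the low dose had the same sign at the high dose, and 3 of 3 higher ones and 1 of 10 lower ones were called there too. Shared controls move both comparisons alike, and how many such agreements they alone give was not simulated. The covariance of the fold changes over 19714 features was 0.16 (jackknife SE 0.0909), with 0.0774 in simulations of unchanged groups against shared controls. It was 0.0601 when the controls were split between the doses (from -0.0209 to 0.139 over 18 splits). The correlation across features, which are not independent replicates, was 0.512 against 0.499 in the simulations and 0.155 with split controls.

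Females and males were compared over all doses, 9 pools against 9, as a reference for the size of a known difference. The yolk precursor gene vtg3 was higher in females by 13.32 (SE 0.335, limma adjusted p = 1.05e-12; well above background on 7 of 9 male arrays), vtg2 by 10.66 and vtg4 by 8.73. For vtg1 (chromosome 22, 25203620 to 25203628) the difference of 7.87 (SE 0.234) was 233-fold, from 2.66 ± 0.90 (SD) in males to 10.53 ± 0.29 in females, and within slides it was 7.68, 7.72 and 8.27. The liver protease gene nots was higher by 12.43 (SE 0.277), eevs, for an enzyme of the sunscreen compound gadusol, at least 510-fold (well above background on 2 of 9 male arrays), and crebbpa by 9.64. Also higher were supt3h, for a subunit of a transcription complex, by 9.19, the retinol-binding gene rbp2a by 9.27, with 1 of its 3 probes on that side, and the GTPase gene irgf4 at least 54.2-fold. In males trim35-9 was at least 21.1-fold higher and myo3a at least 3.08-fold. The fatty acid carrier gene slc27a6 (-5.56, SE 0.583), the testosterone-forming hsd17b3 (-4.55, SE 0.541) and lrit3a (-3.91) were male-biased. So were camk2n2a (-3.56; well above background on 4 of 9 female arrays), the carnitine transferase gene cpt1b (-3.40), the amino acid transporter gene slc6a19b (-3.31) and the carbonic anhydrase gene ca9 (at least 4.75-fold; on 1 of 9). Normexp ended the calls of myo3a and ca9, and leaving out the single-fish pools that of slc6a19b. With the slide as a block lrit3a, camk2n2a, cpt1b, slc6a19b and ca9 did not pass, and slc6a19b passed in 4 of 18 fits that left out an array. Within slides slc6a19b stood at 1.83, -4.79 and -3.19. Of the 35 genes named, 30 lay on their side in 9 of 9 pools and the others in at least 8. In all 5422 features passed, 3187 higher in females and 2235 lower, against 2923 and 2819 with quantile normalization and 2724 and 3269 with the deposited values. Normexp gave 8594 and 1868, and the slide as a block 1783 and 350. The median of all features was 0.35 with normexp and -0.10 with the deposited values.

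The lists were compared between females and males in the same way. Of 91 ribosomal protein genes 83 were higher in females and 1 lower (84 and 3 when adjusted over the list alone), among them rplp1 (1.43, SE 0.134) and rps12 (1.33, SE 0.124). The median of 1.11 became 0.10 with quantile normalization. Of 27 cholesterol synthesis genes 22 were higher (23 when adjusted over the list alone), hmgcra by 2.39 (SE 0.262, adjusted p = 1.45e-05) and within slides by 2.49, 2.16 and 1.11. The endoplasmic reticulum stress list had 14 of 38 higher (16 when adjusted over the list alone), including the folding regulator gene xbp1 (2.37, SE 0.236) and sec61b (1.46), with within-slide medians of 0.71, 1.27 and -0.09. Among 28 hepatocyte genes, 10 were higher, such as tat (2.08) and rbp4 (1.35), and 3 lower by either adjustment. That list's median of 0.22 was -0.57 with quantile normalization and -0.03 with normexp, and within slides 0.62, -0.33 and -0.15. In males 19 of 40 conjugation genes were higher (20 when adjusted over the list alone), such as sult1st5 (-1.68) and ugt1b7 (-1.41), as was the efflux pump gene abcc4 (-3.06, SE 0.350). The cytochrome gene cyp2k6 was female-biased by 7.05 (well above background on 4 of 9 male arrays). Intestine markers were lower in females for 13 of 22 genes (17 when adjusted over the list alone), with mep1a.1 at -2.58 and fabp2 at -1.50. The same was seen for 18 of 31 macrophage and neutrophil genes (21 when adjusted over the list alone; ncf1 -1.38) and 10 of 17 lymphocyte genes (zap70 -1.43) by either adjustment. The calls of mep1a.1 and fabp2 ended without the single-fish pools, that of ugt1b7 with normexp and that of rbp4 with quantile normalization. Of these markers mep1a.1, fabp2, ncf1 and zap70 did not pass with the slide as a block, and on slide 1 all 4 were higher in females. There the medians of the intestine, macrophage and lymphocyte markers were 0.48, 0.62 and 0.27, against -1.23, -1.24 and -0.90 on slide 3 and -3.34, -1.76 and -1.35 on slide 4, which holds high-dose female pools 1 and 2 with few intestine transcripts (-0.64 and -1.55). The only male array on slide 1 is control male pool 1, high in oocyte transcripts and with the lowest macrophage level of any male (0.26). The gene kita was higher in females by 0.88 (SE 0.185), with 1 of its 2 probes on that side, and did not pass when these were averaged. Camera called 11 of 34 lists, and the estrogen-responsive genes, with 9 of 18 higher (10 when adjusted over the list alone), alone held with an estimated correlation (adjusted p = 0.00502). The calls of endoplasmic reticulum stress and exocrine pancreas ended with normexp, and that of the interferon response with the slide as a block. That of the hepatocyte markers ended with both and turned to lower in females with quantile normalization. The slide as a block brought calls of cell cycle, acute phase and growth hormone signalling lower and of oxidative phosphorylation higher in females, and normexp called 22 lists.

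**Figure D3:**
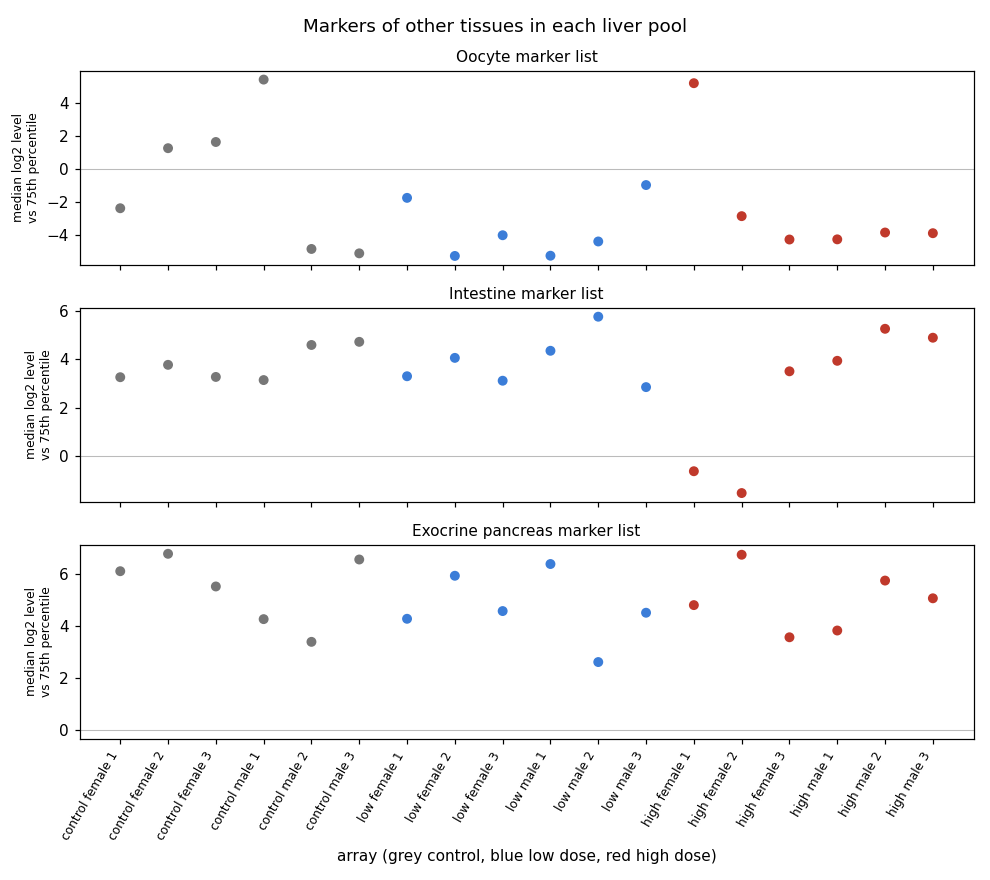
Median level of oocyte, intestine and exocrine pancreas marker genes in each of the 18 liver pools (log2 signal relative to the array's 75th percentile), coloured by dose. Oocyte markers stand at 5.44 in control male pool 1 and 5.22 in high-dose female pool 1, and intestine markers at -0.64 and -1.55 in high-dose female pools 1 and 2.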

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

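The tests of the 3 patterns weighed in this part were chosen only after the result was seen, except that of quantile normalization and that of per2 with the slide as a block, and so were normexp with an offset of 1 and the leaving out of the 2 arrays high in oocyte transcripts. Groups of 3 pools are too small for a test of single outlying pools, so each result in the next 2 paragraphs is a difference between the sexes in their response to a dose, tested as the female effect minus the male effect. The 3 patterns weighed after them were noticed in the values of the comparisons. Chance cannot be excluded for the lists in the next 2 paragraphs. Within the sexes and for the differences at both doses, other splits of the arrays gave a median of 63 called lists, against the real 55.

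At the low dose the test of gene lists separated 11 lists, all lower in females than in males relative to other genes. Their median differences were -0.473 for fatty acid synthesis (camera adjusted p = 0.0103), -0.368 for fatty acid oxidation (0.00165), -0.267 for acute phase and complement (0.00513), -0.413 for the circadian clock (0.00513) and -0.166 for ribosomal proteins (0.0099). They were -0.399 for oxidative phosphorylation (6.4e-09), -0.732 for exocrine pancreas markers (0.0127), -2.98 for endocrine pancreas markers (0.00165) and -0.382 for macrophage and neutrophil markers (0.00946). The stellate, endothelial and biliary markers stood at -0.535 (0.00946) and the muscle and adipose markers at -1.95 (0.0184). The muscle and adipose level was 2.14 in low-dose male pool 2 against -1.97 and -3.63 in pools 1 and 3, and it was also high in high-dose female pool 3 (1.85) and high-dose male pool 3 (1.68), so that the difference at the low dose leans on 1 pool. The endocrine pancreas level was -3.58, -2.24 and 2.77 in the control male pools, so that its difference leans on 2 of them. The ribosomal median was 0.112 with normexp, where the list was called higher in females (adjusted p = 1.09e-05), and 0.00935 with quantile normalization. With normexp the calls of fatty acid synthesis and oxidation, acute phase, the clock, oxidative phosphorylation, exocrine pancreas, macrophages and stellate markers ended, with the slide as a block those of fatty acid synthesis and muscle, and with quantile normalization those of acute phase, ribosomal proteins and exocrine pancreas. Without the 2 arrays high in oocyte transcripts the calls of ribosomal proteins (-0.0524), exocrine pancreas (-0.491), macrophages (0.023) and stellate markers (-0.282) ended. None of the 11 held with an estimated correlation (adjusted p = 0.811 each).

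At the high dose 9 lists differed. The cell cycle list (1.3, camera adjusted p = 9.34e-10) and the estrogen-responsive genes (1.18, 0.000354) lay higher in females. The interferon response (-1.14, 0.00253), bile acid and lipoprotein genes (-0.59, 0.0126), the proteasome (-0.449, 0.0282), endocrine pancreas markers (-3.41, 0.0395), intestine markers (-3.73, 6.27e-09), lymphocyte markers (-0.776, 0.00313) and macrophage and neutrophil markers (-1.21, 8.96e-07) lay lower. The intestine difference leans on high-dose female pools 1 and 2 (levels -0.642 and -1.55, against 3.5 in pool 3), and that of the endocrine pancreas on the same control male pools as at the low dose. Without the 2 arrays high in oocyte transcripts the cell cycle median was 0.503 (adjusted p = 0.023), and the calls of the estrogen-responsive genes (0.784), interferon response (-0.247), bile acid genes (-0.309), proteasome (0.0513) and lymphocytes (-0.464) ended. Normexp ended those of the bile acid genes, proteasome and endocrine pancreas. None held with an estimated correlation (smallest adjusted p = 0.493). Among single features, the probe without a gene symbol and zgc:172170 were the 2 past the threshold. Both were well above background on the 3 high-dose male arrays (means -4.42 and -4.31) and on none of the others. The fitted differences of -3.17 and -4.0 therefore rest on 3 groups at the background level and measure no size.

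The first pattern weighed is the high level of oocyte transcripts in control male pool 1 (5.44) and high-dose female pool 1 (5.22). Female liver RNA mixed into the male pool is argued against, because its vitellogenin level (2.96) lay 0.335 above the mean of the other 8 male arrays, within their range of 1.31 to 4.11, while females stood between 9.79 and 10.8. An exchange of the labels of these 2 pools is argued against too, with a vitellogenin level in the female pool -0.276 from the mean of the other 8 females. Ovary RNA in control male pool 1 stays open: 15 of 15 tested oocyte genes were higher there than in each of the other male arrays, but the pool was singled out by these genes, so that the count decides nothing. No biological explanation was tested.

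The second pattern is that higher calls at the high dose lie among dim probes, where the dimmest of 10 equal bins of features held 251 of them and had a median change of 0.39 (SE 0.0804) against control and 0.477 against the low dose. The background subtraction behind the processed signal stays open: with normexp in its place that median was -0.182 (SE 0.255) against control but 0.215 (SE 0.255) against the low dose, and with an offset of 1 it was -0.282 and 0.556, while the low dose stood at -0.399 and -0.84 against control. Normexp also drops the detrending and adds an offset before the scaling, so it does not change the background subtraction alone. The background subtraction took the place of an earlier explanation, a higher background floor, whose change of 0.0578 (SE 0.167) lay 0.332 under the shift, less than 2 SE from it. That floor, the median of probes never above background, was -7.265 and -7.555 in high-dose male pools 2 and 3, on slide 5. Negative control spots there stood at -8.145 and -7.846. In high-dose male pool 1 the values were -7.208 and -7.323. The shift was 0.548 in males and 0.273 in females. What slide 5 adds to it was not tested, nor was the filter, which keeps probes detected in 1 group alone. The median with quantile normalization, 0.21 (SE 0.054), met the bound of 0.2 set beforehand, which by itself argues against scaling by the 75th percentile. The bound was met by less than the SE, a margin that was not part of it. Scaling is therefore left open. A difference between slides stays open as well, with 0 control or low-dose arrays on the slides of the high dose, and so does the dose itself, which was not tested apart from them.

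The third pattern is the change of clock genes at both doses. A difference between slides stays open. In the slide block, control male pool 1 alone ties the control females to the other slides, and low-dose female pool 3 alone ties the low-dose males. With that block the low-dose per2 change was 0.848 (SE 0.571), within 2 SE of 0, as a difference between slides predicted beforehand. It was also within 2 SE of the value without the block, 1.74. The second reading was added after the value was seen. At the high dose the bmal, clock, npas2 and nfil3 genes stood 1.22 above a group of other clock genes (medians 0.605 and -0.615). That group held the dbp, tef, hlf, per1, per3, nr1d, bhlhe40, bhlhe41 and ciart genes, and per2 was in neither. At the low dose the difference was 0.257, or 0.454 in females and 0.716 in males. The high-dose difference met the bound that sampling at another time of day predicts, set after the values were seen. That explanation stays open, since the files give no sampling times. An effect of the dose on the clock was not tested apart from slides and sampling time and stays open.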

How the results depend on the processing

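Normexp with an offset of 1 and leaving out the 2 arrays high in oocyte transcripts were chosen only after the results were seen. For each value below that moved under an alternative the cause was not tested. Values are counts of features past the threshold unless lists, the covariance or a gene are named.

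With normexp at offset 50 the counts were 2 for the low dose, 211 for the high dose, 32 for the high against the low dose, 0 for the low dose in females, 0 for the high dose in females, 13 for the high dose in males, 0 for the high dose by sex and 10462 for females against males, with 18 lists at the low dose. With normexp at offset 1 they were 2, 122, 45, 0, 0, 8 and 0 for the same comparisons up to the high dose by sex, with 21 lists at the low dose. Under the deposited values they were 6 for the low dose, 1 for the low dose in females and 0 for the high dose by sex. Quantile normalization gave 444 for the high against the low dose, 0 for the low dose in males, 1 for the high dose by sex and 4 lists at the high dose.

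With array weights the counts were 32 for the low dose, 1577 for the high against the low dose, 10 for the low dose in females, 4 for the low dose in males, 12 for the high dose in females, 2005 for the high dose in males and 25 for the high dose by sex. At an adjusted p under 0.1 they were 90 for the low dose, 2671 for the high dose, 1321 for the high against the low dose, 27 and 4 for the low dose in females and males, and 1338 and 770 for the high dose in females and males. An intensity trend with robust eBayes gave 0 for the high dose by sex. The mean of a symbol's probes gave 2 for the low dose and 0 for the low dose in females.

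Without a filter on dim probes the counts were 6 for the low dose, 0 for the low dose in males and 252 for the high dose in females. With only probes well above background in all 18 arrays they were 34 for the low dose, 389 for the high against the low dose, 1 and 1 for the low dose in females and males, 189 for the high dose in males and 0 for the high dose by sex. With only the arrays of the groups compared they were 4 for the low dose, 0 and 1 for the low dose in females and males, 0 and 0 for the high dose in females and males, and 0 for the high dose by sex.

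The slide block gave 0 for the low dose, 165 for the high dose in females, 1 for the low dose by sex, 0 for the high dose by sex and 2133 for females against males, and the covariance was 0.0591. It was 0.0601 with the controls split between the doses. Without the single-fish pools the counts were 0 for the low dose, 658 for the high dose, 365 for the high against the low dose, 0 for the high dose in females, 0 for the high dose by sex and 3364 for females against males, with 10 lists at the low dose and 13 at the high dose. Without the 2 arrays high in oocyte transcripts they were 0 for the low dose, 1012 for the high dose, 0 for the low dose in males, 0 for the high dose in females, 66 for the high dose in males and 0 for the high dose by sex, with 3 lists at the low dose.

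Camera with an estimated correlation called 0 lists at the low dose, 0 at the high dose and 0 within the sexes and for the dose by sex differences, and fry 0, 0 and 1. For females against males they called 1 and 11. The replicate numbers gave no sign of pairing the pools: 3 of 18 same-number pairs correlated over 0.1 (-0.297 to 0.233), with a mean of -0.0628. The mean of 0.0322 for other pairs largely follows from centring each group on its own mean, and groups this small cannot exclude pairing. A replicate block gave 8 for the low dose, 920 for the high dose, 570 for the high against the low dose, 0 and 1 for the low dose in females and males, 7 and 52 for the high dose in females and males, and 0 for the high dose by sex.

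Leaving out each array in turn gave 0 to 50 for the low dose, 809 to 1916 for the high dose, 494 to 1161 for the high against the low dose, 0 to 32 and 0 to 4 for the low dose in females and males, and 0 to 1419 and 22 to 421 for the high dose in females and males. It gave 0 to 1 for the low dose by sex, 1 to 95 for the high dose by sex, 4086 to 5972 for females against males, 3 to 9 lists at the low dose, 6 to 10 at the high dose, 39 to 65 within the sexes and for the dose by sex differences, and a covariance of 0.135 to 0.218.

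Of 209 log2 changes of named genes, 13 of 2831 values under alternatives changed sign, 2323 kept direction and side of the threshold, 478 no longer passed and 17 came to pass. Without single arrays 3383 of 3762 kept both, 349 no longer passed, 30 came to pass and 0 changed sign. For slc38a5a the slide block gave -0.102. With normexp at offsets 50 and 1 npffl stood at -0.278 and -0.472, nup153 at -0.279 and -0.312, aqp8b in females at -0.154 and -0.0803, tle3b at -0.103 and -0.00499 and ppef1 at -0.0732 and -0.00686. At offset 50 raver1 stood at -0.0472 and bsnd at -0.00254.

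Signal over background limits which probes were tested. Between 62.8% and 84.1% of spots were well above background, and 32711 of 43603 probes were kept.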

Other observations

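The splits in this part were planned before the data were examined, and no test here was chosen after its result was seen. Other splits of the same arrays into groups of equal size were fitted in the same way, 100 where more exist.

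For the high dose against control 1 of 100 splits, the real one, gave as many features (1621, the highest other 143), for the high against the low dose 1 of 100 (873, the highest other 220), and for females against males 1 of 100 (5422, the highest other 54). A chance split of the arrays can be excluded for these 3. High-dose arrays share no slide with the other doses, so for both dose comparisons a difference between slides cannot be told apart from the dose. For the low dose against control 2 of 100 splits gave as many (13, the highest other 32), under the 5 in 100 set beforehand. Another split called more features than the doses did, and leaving out single arrays gave 0 to 50. This share is therefore weak ground for excluding chance. The splits take no account of the slides. With the slide as a block 0 features passed in limma for the low dose (725 at an unadjusted p under 0.05), 0 of the 6 named genes among them, so that a difference between slides stays open. For females, however, this block rests on control male pool 1 alone, and for males on low-dose female pool 3 alone.

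For the dose by sex differences these splits decide nothing about chance. At the low dose 0 features passed, so that 100 of 100 splits had to give as many (the highest other 2). At the high dose 10 of 100 gave as many (2, the highest other 1621), but moving dose labels within a sex can turn part of the dose effect into a difference. The split with 1621 exchanges the dose labels in one sex, which turns the difference into the average effect, and so reflects the structure of the samples. Chance cannot be excluded for the gene lists, where 95 of 100 splits gave as many called lists at the low dose (5, the highest other 19), 89 of 100 at the high dose (7, the highest other 19) and 79 of 100 within the sexes and for the differences (55, the highest other 94). The medians of the other splits were 11, 11 and 63 lists, each above the real count. For the covariance of the 2 dose effects 10 of 100 splits gave as large a value (0.16, the highest other 0.275), and chance cannot be excluded.

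Within a sex 10 splits exist, too few for a share under 5 in 100. The low dose gave 3 features in females (1 split as large, the highest other 0) and 2 in males (2 splits, the highest other 2), and the high dose 433 in females (1 split, the highest other 3) and 306 in males (1 split, the highest other 0).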
